A study of Homo sapiens with 6 samples.

How the data were processed

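RNA from cultured human umbilical vein endothelial cells was measured on 6 Affymetrix arrays, 3 from cells given Caskin2 adenovirus and 3 from cells given GFP adenovirus, all grown in medium with 10% serum. Per the labels' protocols, total RNA was extracted on columns with removal of DNA and labelled with a whole-transcript kit. The authors' deposited values are on a log2 scale: robust multi-array averages (RMA) made in Partek 6.5, per the submitters' processing notes, in which background is removed, arrays are brought to a shared distribution and the probes of a set are summarised. The log base is not stated and was taken as 2 from the range of the values, 2.35 to 13.7. Because RMA makes the arrays' distributions alike, a change in total mRNA per cell cannot be seen in these values, and every change is relative to the other genes. The labels speak of a transcriptome array and a whole-transcript kit, whereas the platform annotation pairs the values with probe sets of a 3'-directed array, and this was left unresolved. The genome build is not given in the sources used here, so no coordinates are given.

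The platform annotation gave 1 gene symbol to 19070 of 22277 probe sets, several to 1043 and none to 2164. Of the 62 Affymetrix control probe sets, 6 shared a gene symbol and were left out, so that 19064 probe sets of 11963 genes were used. The gene IDs of 19052 of them were found in the RefSeq gene table of GRCh38.p14, and 0 symbols needed an update. Each gene took the probe set with the highest mean over the 6 arrays. Of 2677 called genes 1063 had another probe set, which passed the same way in 553 and the other way in 7. Of the 133 called genes named by rule 49 had another probe set, of the other sign but not past the test in 5 (APAF1, CAT, NOP16, POSTN and RB1). Some had a probe set of the same sign that did not pass, among them H2BC5, ENG, NR4A1, NRP2, CA12 and SQLE. Probe sets with several symbols or none were not named.

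Groups and replicate numbers were taken from the sample titles. No 2 arrays held the same values. Caskin2 was compared with GFP in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 39 gene lists held 1329 distinct genes, 1110 of them measured, and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. A list needed at least 5 measured members. The design, the lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The rule took CASKIN2, the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays did not overlap between groups, and up to 4 members of each list that passed in its direction with up to 2 in the other. Lists that did not pass gave up to 2 members, or the 1 with the smallest adjusted p. Uncharacterised loci, pseudogenes, non-coding RNAs, receptor segments and symbols that end in P and a digit were left out of the largest changes.

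The alternatives were the replicate number as a block, quantile normalization of the values again, centring on array medians, dropping the dimmest 40% of genes, averaging the probe sets of a gene, testing every probe set, a variance prior with trend and robust fitting, no moderation, array weights, a tested fold of 1.2 (treat), a threshold of 0.01, camera with an estimated correlation, fry, and leaving out each array in turn. Scaling to the 24 poly-A control probe sets was added after the data were seen. The steps were tested on simulated data for this comparison, with 200 of 11963 genes changed. At a log2 change of 0.5, 81.5% of the changed genes were called and 6.3% of calls were unchanged genes. At a change of 1 these were 98.5% and 6.2%, and at 0.2 no gene was called. In the data 2677 genes were called, far more than were changed in the simulation, so these rates do not carry over to the data. Changes near 0.2 did pass there, such as BMP4 at -0.20 and PMVK at 0.19. Camera called 0 lists in 40 unchanged simulated data sets and the shifted list in 20 of 20 sets with a shift of 0.2, with genes simulated as independent. In the data the estimated correlation was 0.53 for the mitosis list, so these list rates do not carry over either.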

Results

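Human umbilical vein endothelial cells, primary cells that line a large vein, carried either an adenovirus for human Caskin2 variant 1 or one for green fluorescent protein (GFP), the virus control. Caskin2 is a scaffold protein of the Caskin family. Virus was given at about 5e+08 plaque-forming units per ml and RNA was taken from 1000000 cells after 24 hours of recovery. Each of the 2 groups held 3 arrays, described in the labels as technical replicates. P-values therefore measure the spread between these 6 arrays and not between separate cultures. The table gave 22277 probe sets, from which 11963 genes took 1 value each. Array medians lay between 6.04 and 6.05 on the log2 scale, and the number of arrays limits the precision. Pearson correlations over all probe sets ranged from 0.998 to 0.999 within groups and from 0.994 to 0.996 between groups. All comparisons are Caskin2 relative to GFP and address which transcripts differ between cells given the Caskin2 virus and cells given the GFP virus.

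CASKIN2 itself gave signals that lay close together in the 2 groups. The brighter of its 2 probe sets read 6.70 ± 0.061 in the Caskin2 arrays and 6.52 ± 0.087 in the GFP arrays (log2, mean ± SD, n = 3). The difference was 0.18 with a standard error of 0.057, which is 1.13-fold, and did not pass the test (limma adjusted p = 0.062). The dimmer probe set read 6.46 ± 0.081 and 6.29 ± 0.0071, a difference of 0.17 (limma adjusted p = 0.0544 over the 19064 probe sets used). On both probe sets the 3 Caskin2 arrays lay above the 3 GFP arrays. The unadjusted 95% intervals of the differences ran from 0.042 to 0.32 and from 0.053 to 0.29 (log2). Their standard errors came from the fit over these 19064 probe sets, and their degrees of freedom from the gene-level fit. Both intervals lay above 0 and ended at 1.25-fold and 1.23-fold. Whether these probes lie inside the sequence carried by the virus is not known here, so the level does not check the group labels, and every direction below rests on the labels. The adjusted p of the brighter probe set fell under 0.05 in 5 of 14 alternatives and ranged from 0.0237 to 0.833, while that of the dimmer did so in 4 of 14 and ranged from 0.0174 to 0.8. Leaving out GFP replicate 3 gave 0.22 (adjusted p = 0.0409) for CASKIN2 on the brighter probe set, and leaving out Caskin2 replicate 3 gave 0.21 (adjusted p = 0.0452) on the dimmer. With scaling to the poly-A control probe sets the CASKIN2 differences turned to -0.026 and -0.032 (adjusted p = 0.833 and 0.8).

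**Figure D1:**
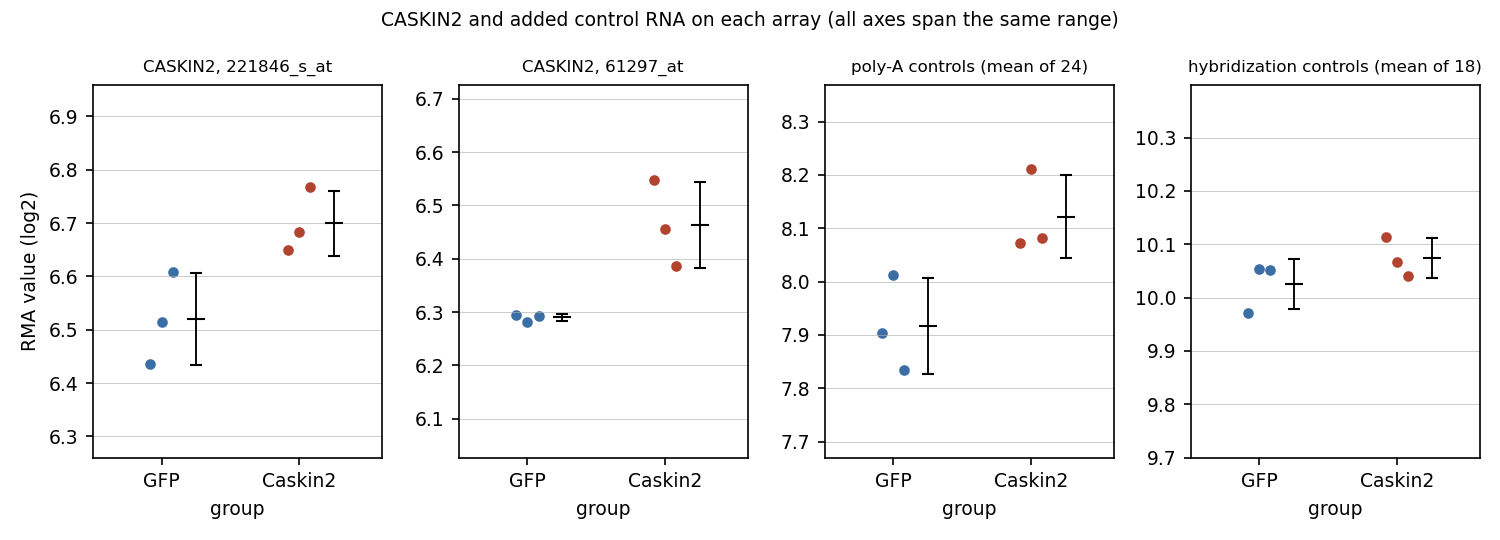
RMA values (log2) of each array for the 2 CASKIN2 probe sets, the mean of the 24 poly-A control probe sets and the mean of the 18 hybridization control probe sets. Points are arrays, the bar beside them is the mean ± SD (n = 3), and all axes span the same range; the Caskin2 points lie above the GFP points for CASKIN2 (6.70 against 6.52 and 6.46 against 6.29) and for the poly-A controls (8.12 against 7.92), and overlap for the hybridization controls (10.07 against 10.03); with poly-A scaling the CASKIN2 differences turn to -0.026 and -0.032.

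Genes of mitosis and of DNA replication fell as lists in the Caskin2 arrays, and the lists of p53 targets and venous endothelial genes rose, as did 14 of 32 immediate early genes, of which 17 did not pass. All 5 list calls were lost with a correlation estimated from the data (adjusted p = 0.443 with an estimated correlation for immediate early genes and 0.249 for each of the others). The largest measured rise was APLNR, the apelin receptor, 5.25-fold higher at 6.61 ± 0.29 against 4.22 ± 0.15 (log2, mean ± SD, n = 3, adjusted p = 6.73e-05). The largest fall among the genes named by rule was KIF15, a mitotic kinesin, 3-fold lower at 5.11 ± 0.20 against 6.69 ± 0.13 (adjusted p = 0.000115). In all, 2677 of 11963 genes (22.4%) passed limma's test at an adjusted p of 0.05. Of these, 1251 were higher and 1426 lower.

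Among the 12 largest rises named by rule, APLNR was followed by PCDH17, a protocadherin, at 3.29-fold (log2 change 1.72, SE 0.058, adjusted p = 2.65e-05). NR4A2, a nuclear receptor of the immediate early class, rose 3.03-fold. POSTN and COL1A2, which encode the matrix proteins periostin and a chain of type I collagen, rose 2.92-fold and 2.6-fold, although a dimmer POSTN probe set read -0.088 and did not pass. CEMIP, a hyaluronan-binding protein, rose 2.65-fold, and STC1, a secreted glycoprotein, rose 2.62-fold. MN1, a transcriptional regulator, rose 2.6-fold and ADAMTS1, a secreted metalloprotease, 2.45-fold. SLCO2A1, a prostaglandin transporter, rose 2.4-fold, OLFML3 2.37-fold and PIK3R3, a regulatory subunit of phosphoinositide kinases, 2.37-fold. The highest adjusted p of these 12 genes was 0.00177, for SLCO2A1. In the GFP arrays APLNR, CEMIP and OLFML3 read 4.22, 4.89 and 4.98, below the array medians, and signal over background was not measured, so the sizes of their folds and the rank of APLNR are uncertain.

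Among the 12 largest falls named by rule, MAD2L1 and TTK, parts of the spindle checkpoint, fell 2.98-fold and 2.86-fold. CENPE, a centromere-bound kinesin, fell 2.57-fold, and PRC1, a bundler of spindle microtubules, 2.6-fold. CDK1, the kinase that drives entry into mitosis, fell 2.6-fold. PBK, a mitotic kinase, fell 2.84-fold and MKI67, the Ki-67 proliferation antigen, 2.77-fold. MCM10 and GINS2, which act at the replication fork, fell 2.65-fold and 2.57-fold. APOBEC3B, a cytidine deaminase, fell 2.61-fold. Outside the cell cycle, CXCL1, a neutrophil-attracting chemokine, fell 2.81-fold (10.32 ± 0.053 in GFP and 8.83 ± 0.088 in Caskin2 arrays). The highest adjusted p of these 12 genes was 0.000239, for MKI67. In the Caskin2 arrays MCM10, KIF15, APOBEC3B and GINS2 read 4.77, 5.11, 5.76 and 5.80, also below the array medians, with the same uncertainty in their folds. RAD51AP1, a recombination factor, fell further (3.06-fold, adjusted p = 5.05e-05) and stands outside the naming rule because its symbol ends like that of a pseudogene, so it was chosen after its values were seen.

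**Figure D2:**
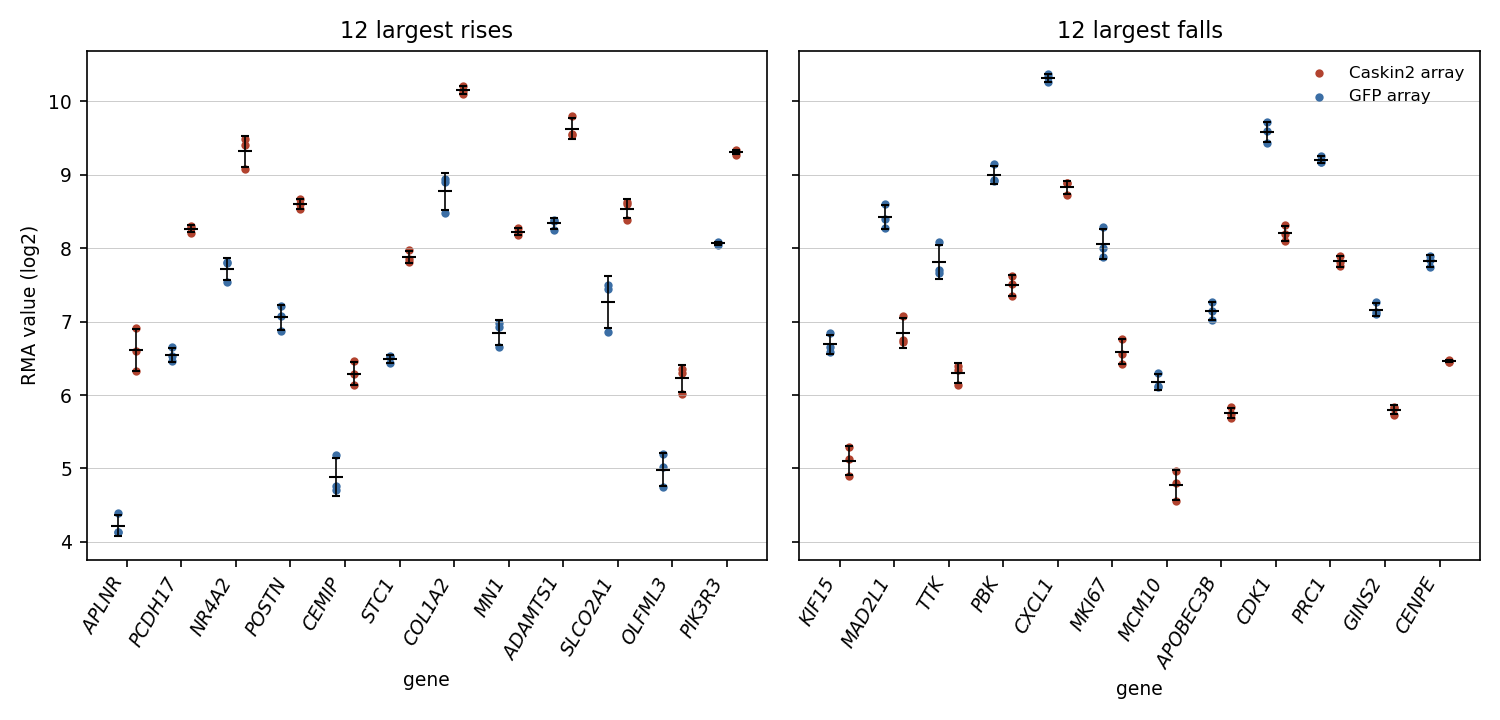
RMA values (log2) of each array for the 12 genes with the largest rise and the 12 with the largest fall that the naming rule allowed. Symbols that end in P and a digit are left out, some with larger changes. Points are arrays, black bars give the mean ± SD (n = 3), and in each gene the 3 Caskin2 arrays lie on one side of the 3 GFP arrays, from APLNR (6.61 against 4.22) to CENPE (6.46 against 7.82).

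Of the 133 called genes named by rule, 21 had a group mean below the array medians, where the size of a fold is uncertain because signal over background was not measured. Besides those above these were SYP, CD14, FBLN2, PROX1, LIN7A, STAB2, MAP2, KRT7, IFI44L, CA12, H2BC5, SELP, LUM and LAMP3. Most changes were small. At least 1.5-fold change was met by 91 genes that rose and 197 that fell, and at least 2-fold by 24 and 75. The median SD within groups was 0.069 on the log2 scale. The arrays of the groups did not overlap for 4882 genes (40.8%), where chance gives 10% if all arrays are independent. The labels call them technical replicates, so any difference between the cultures, whatever its source, can raise this share. Without Caskin2 replicate 1, 830 genes were higher, against 1251 with all 6 arrays. Asking for a change beyond 1.2-fold left 370 genes. Poly-A control RNA, which is added to each sample before labelling, read 0.21 higher in the Caskin2 arrays. Scaling to it, a choice made after seeing the data, moved the median change of all genes from 0.0053 to -0.20. Under that scaling 4.3% of 4998 called genes were higher, against 46.7% without it, and 323 of the 2677 genes turned their sign. Every rise given here is thus relative to the median gene. Of the 133 called genes named by rule, 15 lost their call under it with the direction kept (DTL, CDKN1B, CAT, SESN1, PPP1R16B, CASK, LDB2, LYL1, KDR, PROX1, CNN2, TM7SF2, NDUFA8, CD14 and SYP), and PMVK turned to -0.017.

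Of 39 gene lists fixed before the data were examined, 18 passed the camera test, 10 higher and 8 lower. Camera was run with a preset correlation between genes of 0.01. With an estimated correlation none of the 39 lists passed, 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.249. For each of the 18 lists that was the highest adjusted p among its alternatives. With fry, which does not compare a list with other genes, 25 lists passed, and 17 of the 18 were among them. The 8 lists gained were histones, arterial and Notch, unfolded protein, heat shock, apoptosis, Wnt, smooth muscle and fibroblast, and leukocyte markers. There were 100 genes in more than 1 list. Poly-A scaling lowers every list median by 0.21.

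Genes of mitosis and cytokinesis fell almost as a block. Of 55 measured members 54 were lower and 0 higher, also 54 when adjusted over the list alone, with a median log2 change of -1.11 (2.16-fold, camera adjusted p = 2.69e-43, and adjusted p = 0.249 with an estimated correlation). KIF15, MAD2L1, TTK and PBK had the largest falls. The exception was SPC24, a kinetochore gene, at 0.067 (adjusted p = 0.688). Genes of the G1/S transition and DNA replication fell as well: 43 of 51 were lower and 1 higher (47 and 1 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 1.77e-26, and adjusted p = 0.249 with an estimated correlation). MCM10 and GINS2 led, then GINS1 at 2.51-fold and MCM4, a subunit of the replicative helicase, at 2.46-fold lower. DTL, a ubiquitin ligase adaptor of S phase, rose 1.2-fold (adjusted p = 0.00268).

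Of 22 measured inhibitors of the cell cycle and quiescence genes, 9 rose, 2 fell and 11 did not pass (10 and 2 higher and lower adjusted over the list alone), with a median of 0.11 that was -0.099 with poly-A scaling (camera adjusted p = 0.00735, and adjusted p = 0.342 with an estimated correlation). TOB1, an antiproliferative gene, rose 1.6-fold. The CDK inhibitors CDKN1A, CDKN1C and CDKN1B rose 1.47-fold, 1.43-fold and 1.31-fold. RB1, the retinoblastoma gene, fell 1.28-fold and its relative RBL2 1.14-fold, but neither passed when the probe sets of a gene were averaged (adjusted p = 0.266 and 0.12), and the other RB1 probe set read 0.15 higher. RBL2 also lost its call without Caskin2 replicate 1, GFP replicate 1 or GFP replicate 3 (adjusted p = 0.0663, 0.0534 and 0.0606).

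Targets of p53 rose: 15 of 26 were higher and 2 lower (16 and 2 adjusted over the list alone), with a median of 0.26 that was 0.053 with poly-A scaling (camera adjusted p = 1.45e-07, and adjusted p = 0.249 with an estimated correlation). FAS, a death receptor, rose 2.3-fold and CYFIP2 rose 1.73-fold. PPM1D, a phosphatase that dampens p53 signalling, rose 1.65-fold and TP53I3 1.54-fold. PMAIP1, the pro-apoptotic NOXA gene, fell 1.37-fold. APAF1, the apoptosome scaffold, fell 1.38-fold on its brightest probe set, while its other probe sets read 0.057 and 0.096 higher and their average did not pass (adjusted p = 0.132). FOXO targets were higher in 13 of 30 and lower in 4 (15 and 4 adjusted over the list alone), with a median of 0.17 that was -0.039 with poly-A scaling (camera adjusted p = 0.00914, and adjusted p = 0.342 with an estimated correlation). KLF4, a transcription factor also in the shear list, rose 1.81-fold, CAT, which encodes catalase, 1.32-fold and SESN1 1.31-fold, although the dimmest CAT probe set read -0.099 and did not pass. Within the FOXO list the chemokine receptor CXCR4 fell 1.57-fold and the angiopoietin ANGPT2 1.28-fold.

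Of 14 measured venous endothelial genes 9 rose and 0 fell, also 9 and 0 adjusted over the list alone, with a median of 0.26 that was 0.054 with poly-A scaling (camera adjusted p = 1.65e-05, and adjusted p = 0.249 with an estimated correlation). After APLNR came SELP, the adhesion receptor P-selectin, at 2.32-fold, NRP2, a semaphorin and VEGF-C co-receptor, at 1.88-fold, and FLRT2 at 1.55-fold. The NRP2 probe set used read 0.91, while the dimmer ones read 0.16, 0.17, 0.30 and 0.39. Those at 0.16 and 0.17 did not pass. Lymphatic endothelial genes were higher in 6 of 14 and lower in 0 (7 and 0 adjusted over the list alone), with a median of 0.15 that was -0.054 with poly-A scaling (camera adjusted p = 0.00869, and adjusted p = 0.342 with an estimated correlation). LYVE1, a hyaluronan receptor, rose 1.39-fold, STAB2 1.38-fold and PROX1, the lymphatic transcription factor, 1.31-fold. Genes of pan-endothelial identity were higher in 11 of 34 and lower in 2 (12 and 3 adjusted over the list alone), with a median of 0.10 that was -0.10 with poly-A scaling, where the list did not pass (adjusted p = 0.11; camera adjusted p = 0.00309 without that scaling, and adjusted p = 0.506 with an estimated correlation). EMCN rose 1.61-fold, LDB2 1.33-fold, LYL1 1.32-fold and KDR, the main VEGF receptor, 1.22-fold. ESM1, a secreted proteoglycan of sprouting endothelium, fell 2.29-fold and ENG, the TGF-beta co-receptor endoglin, 1.28-fold. A dimmer ENG probe set read -0.015 and did not pass.

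Genes of the laminar shear and KLF2/KLF4 program were higher in 10 of 24 and lower in 3 (11 and 3 adjusted over the list alone), with a median of 0.065 that was -0.14 with poly-A scaling (camera adjusted p = 0.00957, and adjusted p = 0.342 with an estimated correlation). HMOX1, which encodes heme oxygenase, rose 1.75-fold, THBD, the anticoagulant receptor thrombomodulin, 1.64-fold and ASS1 1.49-fold. SLC7A5, an amino acid transporter, fell 1.49-fold. Immediate early genes were higher in 14 of 32 and lower in 1 (20 and 3 adjusted over the list alone), with a median of 0.25 that was 0.044 with poly-A scaling (camera adjusted p = 3.38e-05, and adjusted p = 0.443 with an estimated correlation). Besides NR4A2, FOSB rose 1.67-fold and NR4A1 1.65-fold. FOSB was 1 of 14 named genes that lost their call without variance moderation (adjusted p = 0.0851 for FOSB). Another NR4A1 probe set read 0.014 and did not pass, while the dimmest read 0.53 and passed. EGR3 was 1.66-fold higher (adjusted p = 0.0267), a call lost without Caskin2 replicate 2 or 3 or GFP replicate 1 or 2 (adjusted p = 0.0695, 0.0573, 0.0759 and 0.0825) and with the replicate number as a block (adjusted p = 0.0573). FOSL1 fell 1.6-fold.

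Genes of the extracellular matrix and basement membrane were higher in 16 of 51 and lower in 3 (22 and 3 adjusted over the list alone), with a median of 0.13 that was -0.075 with poly-A scaling (camera adjusted p = 0.000392, and adjusted p = 0.408 with an estimated correlation). POSTN and COL1A2 led, FBLN2 and LUM, the proteoglycan lumican, rose as well, from GFP levels of 4.38 and 5.95 that lay below the array medians. Smooth muscle and fibroblast markers, which also hold POSTN, COL1A2 and LUM, were higher in 4 of 22 and passed in 4 of 17 alternatives. LOX, a collagen crosslinking enzyme, fell 1.28-fold. COL13A1 was 1.18-fold lower (adjusted p = 0.0342), a call lost without Caskin2 replicate 1, 2 or 3 or GFP replicate 2 or 3 (adjusted p = 0.104, 0.0584, 0.0703, 0.0697 and 0.0628). Targets of TGF-beta and BMP were higher in 15 of 32 and lower in 2 (16 and 2 adjusted over the list alone), with a median of 0.15 that was -0.053 with poly-A scaling (camera adjusted p = 0.000571, and adjusted p = 0.338 with an estimated correlation). SMAD7, an inhibitor of the pathway, rose 1.64-fold, BAMBI, a decoy receptor, 1.44-fold, HEY1 1.41-fold and SNAI1 1.38-fold. BMP4 fell 1.15-fold.

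Ribosome biogenesis genes fell in 17 of 28 and rose in 0 (18 and 0 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 3.72e-08, and adjusted p = 0.249 with an estimated correlation). NOP16 fell 1.45-fold, DDX21 1.43-fold, UTP20 1.4-fold and NOLC1 1.36-fold, although a dimmer NOP16 probe set read 0.17 higher (adjusted p = 0.0527). Proteasome genes fell in 13 of 27 and rose in 0 (19 and 0 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 6.0e-06, and adjusted p = 0.342 with an estimated correlation). PSMD14 fell 1.31-fold, PSMD2 1.2-fold, PSMD1 1.19-fold and PSMA3 1.18-fold. Cholesterol synthesis genes fell in 11 of 19 and rose in 2 (13 and 2 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.000392, and adjusted p = 0.342 with an estimated correlation). DHCR7 fell 1.57-fold, ACAT2 1.52-fold, SQLE, which encodes squalene epoxidase, 1.48-fold and MSMO1 1.42-fold. The dimmer SQLE probe sets read -0.23 and -0.27 and did not pass. TM7SF2 rose 1.25-fold. PMVK was 1.14-fold higher (adjusted p = 0.0331), a call lost without Caskin2 replicate 1 or 3 or GFP replicate 2 or 3 (adjusted p = 0.105, 0.0994, 0.0963 and 0.0725). With poly-A scaling PMVK read -0.017 and did not pass (limma adjusted p = 0.889).

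NF-kB inflammatory, adhesion and chemokine genes fell in 13 of 43 and rose in 4 (14 and 4 adjusted over the list alone), with a median of -0.093 (camera adjusted p = 0.0364, and adjusted p = 0.475 with an estimated correlation). The chemokines CXCL1, CXCL8 and CCL2 fell 2.81-fold, 2.35-fold and 1.82-fold, and PTX3, a secreted pattern recognition protein, 1.8-fold. IL33, a nuclear cytokine of resting endothelium, rose 2.35-fold and SELP 2.32-fold. This list did not pass without Caskin2 replicate 3 or GFP replicate 3 (adjusted p = 0.0633 and 0.0683), nor with the dimmest genes dropped (adjusted p = 0.107), and its adjusted p ranged from 0.00497 to 0.475. The NF-kB median was -0.022 without Caskin2 replicate 3, -0.039 without Caskin2 replicate 1, -0.0401 without GFP replicate 2 and -0.048 without GFP replicate 3. Hypoxia and glycolysis genes fell in 14 of 36 and rose in 6 (18 and 7 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0448, and adjusted p = 0.342 with an estimated correlation). HK2, which encodes hexokinase, fell 1.86-fold, LDHA 1.41-fold and ENO1 1.35-fold. CA12 was 1.32-fold lower (adjusted p = 0.0285), a call lost without Caskin2 replicate 1 or GFP replicate 1 or 2 (adjusted p = 0.0593, 0.0832 and 0.0989). Another CA12 probe set also passed, at -0.34, while the rest read -0.31 to -0.0061 and did not pass. ANGPTL4 rose 1.57-fold and SLC2A3, a glucose transporter, 1.47-fold. The hypoxia list did not pass without Caskin2 replicate 2 or 3 or GFP replicate 1 (adjusted p = 0.073, 0.0583 and 0.0563) and passed in 8 of 17 alternatives, with an adjusted p from 0.00107 to 0.342.

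Oxidative phosphorylation genes were lower in 7 of 51 and higher in 1 (5 and 1 adjusted over the list alone), with a median of -0.022 (camera adjusted p = 0.0469, and adjusted p = 0.771 with an estimated correlation). NDUFB6 fell 1.21-fold, CYC1 1.19-fold and NDUFA9 1.17-fold, while NDUFA8 rose 1.16-fold. NDUFS1 was 1.17-fold lower (adjusted p = 0.0161), a call lost without Caskin2 replicate 1 (adjusted p = 0.0563). This list passed in 5 of 17 alternatives (adjusted p from 0.0209 to 0.771) and was lost without Caskin2 replicate 2 or GFP replicate 1 (adjusted p = 0.223 and 0.168) and with the replicate number as a block (adjusted p = 0.0571). Its median was -0.0091 without Caskin2 replicate 2, -0.014 without GFP replicate 1, -0.035 without GFP replicate 3 and -0.037 without Caskin2 replicate 1.

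**Figure D3:**
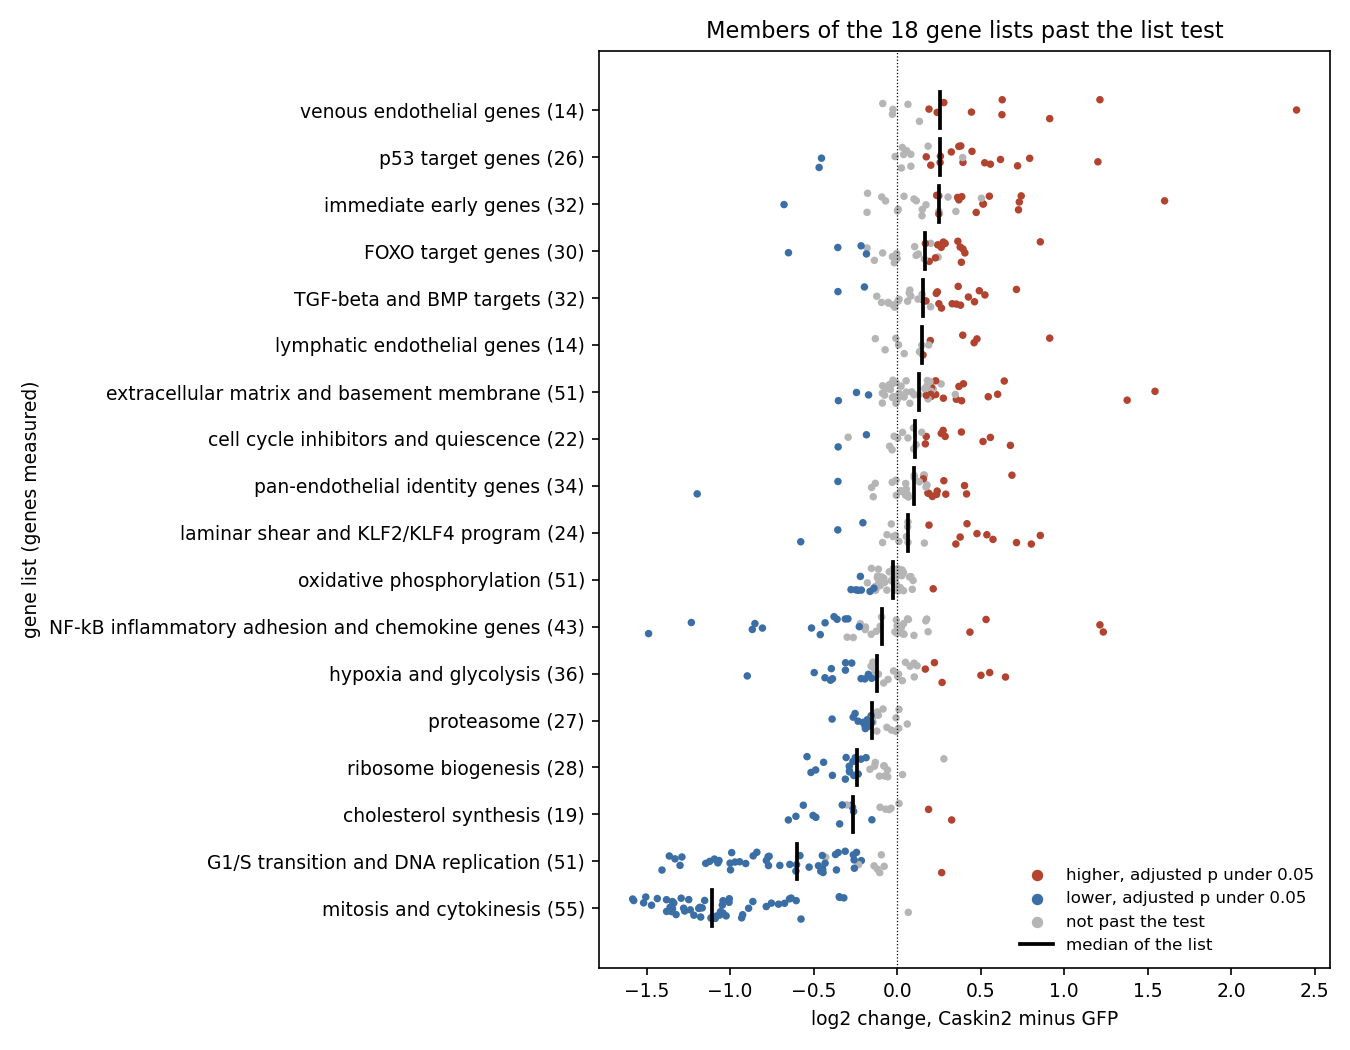
Log2 change (Caskin2 minus GFP, x axis) of each measured member of the 18 lists that passed the list test, 1 line per list with the number measured. Points are genes, coloured by whether they were higher or lower past an adjusted p of 0.05, and the vertical bar is the list median, from 0.26 for venous genes to -1.11 for mitosis; with poly-A scaling the medians of the FOXO, TGF-beta, lymphatic, matrix, cell cycle inhibitor, pan-endothelial and shear lists lie below 0.

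The other 21 lists did not pass, and with poly-A scaling every median above 0 among them lay below 0. Unfolded protein and integrated stress response genes were higher in 5 and lower in 12 of 42 (5 and 15 adjusted over the list alone; camera adjusted p = 0.0682), with ASNS, asparagine synthetase, and PHGDH lower by 1.76-fold and 1.6-fold. Without GFP replicate 2 this list passed (adjusted p = 0.0454), and over the alternatives its adjusted p ranged from 0.00677 to 0.443. Arterial and Notch pathway genes were higher in 10 and lower in 3 of 26 (11 and 4 adjusted over the list alone; adjusted p = 0.0696, range over the alternatives 0.0261 to 0.506), with HEY1 higher and CXCR4 lower. Type I interferon response genes, of interest after any virus, were higher in 10 and lower in 2 of 50 (11 and 2 adjusted over the list alone; adjusted p = 0.0841). IFI44L was 1.38-fold higher and LAMP3 1.45-fold lower, and without GFP replicate 3 the list passed (adjusted p = 0.0344; range over the alternatives 0.0344 to 0.508). Cytosolic ribosomal protein genes were higher in 0 and lower in 0 of 52 (0 and 0 adjusted over the list alone; adjusted p = 0.109), with RPS9 at 0.11 (adjusted p = 0.1) and 1 member at an unadjusted limma p under 0.05. Replication-dependent histones were higher in 3 and lower in 0 of 27 (2 and 0 adjusted over the list alone, camera adjusted p = 0.112). Among them were H2BC5 at 1.57-fold and H2BC12 at 1.45-fold. The other H2BC5 probe set read 0.055 and did not pass. MHC class I antigen presentation genes were higher in 0 and lower in 1 of 18 (0 and 1 adjusted over the list alone; adjusted p = 0.945), the gene being PSMB9 at 1.4-fold.

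Genes of the cytosolic heat shock response list were higher in 3 and lower in 7 of 20 (3 and 8 adjusted over the list alone, camera adjusted p = 0.164). Among them HSPE1 was 1.46-fold and HSP90AA1 1.26-fold lower. The Caskin family and its reported partners were higher in 4 and lower in 2 of 20 (5 and 2 adjusted over the list alone; adjusted p = 0.164). CASK, the kinase-like scaffold, was 1.28-fold higher. LIN7A was 1.36-fold higher (adjusted p = 0.0227), a call lost without Caskin2 replicate 1, 2 or 3 or GFP replicate 1 (adjusted p = 0.0652, 0.0536, 0.0589 and 0.0502). Wnt and beta-catenin pathway genes were higher in 6 and lower in 2 of 23 (6 and 2 adjusted over the list alone; adjusted p = 0.196), with DKK1, a secreted Wnt antagonist, 1.82-fold lower and CCND2 1.57-fold higher. Tip cell and sprouting genes were higher in 12 and lower in 10 of 41 (16 and 11 adjusted over the list alone; adjusted p = 0.207), led by NR4A2 and STC1. Endothelial junction genes were higher in 5 and lower in 3 of 24 (9 and 5 adjusted over the list alone; adjusted p = 0.483), with GJA4 and JUP both 1.39-fold higher. Nitric oxide and vasoactive genes were higher in 9 and lower in 4 of 41 (10 and 6 adjusted over the list alone; adjusted p = 0.514), with PTGS1, a cyclooxygenase, 1.74-fold and RAMP2 1.65-fold higher.

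Actin cytoskeleton and focal adhesion genes were higher in 3 and lower in 7 of 48 (3 and 7 adjusted over the list alone; adjusted p = 0.603), with TAGLN2 1.26-fold lower and CNN2 1.26-fold higher. YAP/TAZ and SRF targets were higher in 6 and lower in 5 of 26 (7 and 6 adjusted over the list alone; adjusted p = 0.945), with ANKRD1 1.95-fold and TNFRSF12A 1.63-fold lower. NRF2 targets were higher in 4 and lower in 7 of 24 (4 and 8 adjusted over the list alone; adjusted p = 0.787), with TXNRD1, thioredoxin reductase, 1.8-fold lower and HMOX1 higher. Protein phosphatase 1 subunits were higher in 3 and lower in 2 of 23 (3 and 2 adjusted over the list alone; adjusted p = 0.812), with PPP1R3C 1.68-fold and PPP1R16B 1.18-fold higher. Apoptosis regulators were higher in 4 and lower in 9 of 38 (5 and 9 adjusted over the list alone; adjusted p = 0.945), with FAS higher and BIRC5, which encodes survivin, 2.03-fold lower. The median and the mean or the test differed in sign for 7 lists: nitric oxide, NRF2, phosphatase 1, apoptosis, YAP/TAZ, epithelial and MHC class I.

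Markers of other cell types did not pass as lists in the planned test. Smooth muscle and fibroblast markers were higher in 4 and lower in 0 of 22 (4 and 0 adjusted over the list alone; adjusted p = 0.119), and POSTN and COL1A2, which the matrix list also holds, were the largest. The median of these markers was 0.0061. This list passed with the dimmest genes dropped (adjusted p = 0.0157), with probe sets averaged (0.0448), with fry (0.00268) and with poly-A scaling (0.000486, higher relative to the other genes although its median was -0.20), and its adjusted p ranged up to 0.342. Leukocyte markers were higher in 2 and lower in 1 of 24 (2 and 1 adjusted over the list alone, camera adjusted p = 0.776), and passed with fry (adjusted p = 0.0376). LAPTM5 was 1.36-fold higher, and CD14 was higher from a GFP level of 4.11 that lay below the array medians. Epithelial markers were higher in 1 and lower in 2 of 18 (1 and 2 adjusted over the list alone; adjusted p = 0.945), with KRT19 1.4-fold higher and KRT7 1.29-fold lower. Neuronal and synaptic genes were higher in 3 and lower in 2 of 27 (3 and 2 adjusted over the list alone; adjusted p = 0.929), with MAP2 1.37-fold and SYP 1.22-fold higher.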

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

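The tests of array-wide scaling, of the CASKIN2 probe sets and of the control probe sets, and the poly-A scaling, were chosen after the results were seen.

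The fall of the mitosis and replication lists was set against 4 explanations. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real 1 of them called 2677 genes with limma, and the highest of the others called 0. At an unadjusted p under 0.05 the others held 202 to 467 genes against 4171. Every other split puts arrays of both groups on each side, so the group difference adds to its spread. The counts of the other splits therefore do not measure chance. An array-wide scaling error tied to brightness would move genes of like brightness alike. Of 10000 random lists matched on mean expression, 0% had a median as low as either list. The lowest random medians were -0.10 and -0.088 against -1.11 and -0.60. The 2 lists were already known to lie below other genes, so this repeats the camera result for genes of like brightness. It does not address normalization errors that are not tied to brightness. For a difference in RNA quality or 3' bias, the control probe sets of ACTB and GAPDH were read. Their 3' minus 5' difference differed by -0.0466 (ACTB) and -0.024 (GAPDH) between the groups, so these 2 transcripts gave little sign of unequal 3' bias. With only 2 transcripts and the labelling kit unresolved, this does not decide whether RNA quality differed. A biological explanation, p53 acting through CDKN1A, needs CDKN1A to be higher, and it was, by 0.56; this goes with the hypothesis and does not show it, since the cell cycle of these cultures may have differed for other reasons.

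The close CASKIN2 signals in both groups are a surprise in cells given a Caskin2 virus. A single array in the wrong group is argued against because every correlation within a group exceeded every one between groups, by 0.0021 at the least. Probe sets outside the expressed sequence stay open: of the 2 probe sets, 0 have a position relative to the viral insert that is known here. Probe sets too dim to respond stay open as well, since levels of different probe sets are not comparable and the 53.9 percentile of the dimmer one among all probe sets does not show signal over background.

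Poly-A control probe sets, which are not part of the gene comparison, were higher in the Caskin2 arrays: the 24 sets averaged 8.12 ± 0.078 against 7.92 ± 0.09 (log2, mean ± SD, n = 3), a difference of 0.2051 with 24 of 24 sets higher (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays can give). Brighter hybridization or scanning is argued against by the hybridization controls, which are added after labelling and differed by 0.0484 (exact permutation p = 0.3). Unequal amounts of control RNA or of mRNA in the samples stay open, since the amounts are known here for 0 of the 6 arrays. Differences in RNA input, its quantification or mRNA per cell were not separated.

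Probe sets left out of the gene comparison were tested in a fit over all 22277 probe sets, controls included. Of 2108 unnamed probe sets outside the controls 232 passed the test, 104 higher and 128 lower. Of 1043 probe sets with several gene symbols 167 passed, 83 higher and 84 lower. Where every probe set outside the controls was tested, 3870 of 22215 passed, a larger share than in either kind.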

How the results depend on the processing

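Limma's total of 2677 genes stayed between 1908 and 3375 wherever genes were tested, except at a tested fold of 1.2 (370 genes, 123 higher and 247 lower), at an adjusted p of 0.01 (1395 genes, 584 higher and 811 lower) and with poly-A scaling, chosen after seeing the data (4998 genes, 214 higher and 4784 lower; at least 1.5-fold, 40 higher and 442 lower). The first of these asks for more and the second is stricter by construction; poly-A scaling lowers each gene in the Caskin2 arrays relative to GFP by construction, and the median of all genes moved from 0.0053 to -0.20. Testing each of 22215 probe sets called 3870 of them, 148 higher by at least 1.5-fold, where more features were tested. Leaving out each array in turn gave 1908 to 2198 genes, 830 to 1045 of them higher, with fewer arrays in the fit. The CASKIN2 difference passed on repeated quantile normalization (0.19 and 0.19), median centring (0.19 and 0.18) and without the dimmest 40% of genes (0.18 and 0.17, where fewer genes are tested), and ranged from 0.14 to 0.22 and from 0.13 to 0.21 without single arrays; apart from the filter the cause was not tested. Whether the replicate number pairs the arrays cannot be told from so few arrays. Deviations of same-numbered arrays correlated at 0.10, 0.034 and -0.025, the first being the highest of all pairs. Caskin2 replicates 2 and 3 correlated best with GFP replicates 3 and 2 (0.059 and 0.037). With the replicate block 2281 genes passed, 2159 of them among the 2677, CASKIN2 passed on the brighter probe set (0.18, adjusted p = 0.0393), and 17 of 18 lists and 132 of 133 named genes kept their calls; the oxidative phosphorylation list (adjusted p = 0.0571) and EGR3 (adjusted p = 0.0573) did not.

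Of the 18 lists, 14 to 18 kept their call under each alternative in which they could be tested, except with an estimated correlation, where 0 of 18 did. Lower lists numbered 5, against 8, without the dimmest 40% of genes and at an adjusted p of 0.01; with an estimated correlation the counts were 0 in all, 0 higher and 0 lower. The number of lists called also differed between array splits. The real split called 18 lists, 1 of 10 splits gave as many and the others called 4 to 12. Those others hold arrays of both groups on each side, so their counts do not measure chance, and 10 splits are too few for a share under 0.05. Of 133 named genes 117 to 133 kept their call in each alternative applied to them, which leaves out the tested fold and the stricter threshold (121 of 121 where the dimmest genes were dropped). The 14 lost without variance moderation were LIN7A, STAB2, GJA4, FBLN2, LOX, COL13A1, MSMO1, TM7SF2, PMVK, CA12, FOSB, EGR3, NDUFS1 and CD14. PMVK alone turned its sign, without passing, at -0.0172 with poly-A scaling (limma adjusted p = 0.889), which moves all genes down. Dim probe sets limit what arrays show, and 12 called named genes fell among the dimmest 40%.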

Other observations

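The 9 lists here were written after the gene table was seen, and the tests for homologous recombination, condensin, cAMP and aquaporin genes were chosen after their largest members were seen. All 9 passed camera when adjusted over these lists, and none did with an estimated correlation (adjusted p = 0.108 to 0.216). Among condensin, cohesin and centromere genes 20 of 30 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.60, adjusted p = 3.67e-14), such as CENPU at 2.32-fold, the centromere histone chaperone HJURP at 2.18-fold and the condensin subunit NCAPG at 2.08-fold. Homologous recombination and Fanconi genes fell in 10 of 22 with 0 higher (11 and 0 adjusted over the list alone; median -0.15, adjusted p = 1.96e-05), with RAD51AP1 at 3.06-fold and FANCI at 1.83-fold. Pre-mRNA splicing factors fell in 31 of 54 with 0 higher (34 and 0 adjusted over the list alone; median -0.18, adjusted p = 7.88e-12), with SNRPA1 at 1.56-fold and SRSF7 at 1.44-fold. Nuclear import and nuclear pore genes fell in 24 of 49 with 0 higher (26 and 0 adjusted over the list alone; median -0.16, adjusted p = 4.43e-10), with NUP205 at 1.44-fold and the export receptor CSE1L at 1.4-fold. Aminoacyl-tRNA synthetases fell in 10 of 21 (12 adjusted over the list alone; median -0.15, adjusted p = 1.47e-06), led by IARS1 at 1.37-fold, and mitochondrial ribosomal proteins in 18 of 46 (21 adjusted over the list alone; median -0.11, adjusted p = 4.48e-06), led by MRPL39 at 1.32-fold.

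Targets of cAMP and CREB rose in 13 of 24 with 0 lower (15 and 0 adjusted over the list alone; median 0.33, adjusted p = 4.82e-06). SIK1, a kinase induced by cAMP, rose 1.91-fold and RGS2, a brake on G protein signalling, 1.53-fold; 11 of the 24 genes also stand in a fixed list. Lysosomal and autophagy genes rose in 19 of 51 and fell in 3 (23 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.000634). Poly-A scaling lowers each gene by 0.21, so the medians of the lysosomal and aquaporin lists turn below 0 under it. SCARB2 rose 1.38-fold, TPP1 1.32-fold and ASAH1, acid ceramidase, 1.31-fold, whereas NPC1 fell 1.21-fold. Of 9 aquaporins 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.0744, adjusted p = 0.00733): AQP3 1.96-fold, AQP1 1.93-fold and AQP5 1.87-fold.

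Because the recombination, condensin, cAMP and aquaporin lists were written after their largest members were seen, their tests do not decide whether these groups moved as a whole. A retest without the members among the 100 or 200 largest changes, the second limit added because the first left out 0 aquaporins, removes genes by the outcome itself and decides nothing either. The cAMP list did not pass with an estimated correlation (adjusted p = 0.181), and whether cAMP or CREB signalling itself differed was not tested.

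DLGAP5, a mitotic spindle protein, fell 2.71-fold (adjusted p = 0.000163) and PPFIBP2, a liprin, rose 2.53-fold (adjusted p = 0.000158); like RAD51AP1 their symbols end in P and a digit, and they were chosen after their values were seen.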
